A study of Aspergillus nidulans with 12 samples.

How the data were processed

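Poly(A) RNA of Aspergillus nidulans cultures was sequenced from libraries made with a Nextera kit, per the labels. The 12 libraries came from wild type (strain A1153) and strains labelled rimO deletion and rimO overexpression, at 17 h and at a late harvest of 48 h (54 h for the deletion strain), with 2 cultures per group. The submitters' processing notes name Trimmomatic, BWA, HTSeq, limma and edgeR without versions. The genome build is not given in the sources used here, nor is the strandedness of the counting. The deposited counts are whole numbers of reads per gene, 1 column per library, and no step beyond the tools above is recorded for them. A second set of deposited columns gives log2 RPKM per gene for each of the 6 groups, not for each culture, so no test could be run on it and it was not used further.

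The count table had 10727 entries. Of these, 15 repeated an identifier with the same values and were left out, and 31 were upstream open reading frames by their identifiers, which held 0.000199% of the counts and were left out, leaving 10681 genes. Libraries held 9269951 to 17891416 counts. Chi-square per degree of freedom between the 2 cultures of a group was 10 to 47.3, so cultures differed by more than counting error, and the fits estimate that spread (common biological coefficient of variation 8.2%). Bounds for genes with no count in a group take 3 counts over the group, and ratios with 1 to 3 counts have a 95% counting interval. Both cover counting error only, since reads are not independent molecules.

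Counts were tested with edgeR 4.0.16 (R 4.3.3) in 1 quasi-likelihood fit over the 12 libraries and 6 groups, with TMM scaling and filterByExpr, which kept 9670 genes and left 1011 below the filter. The fit had 6 residual degrees of freedom and 7.73 prior degrees of freedom. The 9 contrasts were each labelled strain against wild type at each harvest, late against early in each strain, and the difference of that change from wild type. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, and the number of calls with a log2 change of at least 1 was counted beside it. TMM takes most genes as unchanged between libraries, and in most contrasts most genes were called, so shifts of the median gene under other scalings are given. Interactions and comparisons of the late harvests carry the 6 h difference in harvest time of the deletion-labelled strain.

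Gene lists were written from general knowledge before the data were examined, as were the tests, the rule for named genes and the alternatives planned. Of 41 lists, 9 searched a product description, which the reference gene table lacks, and 8 of those stayed empty. The remaining one held autophagy genes by symbol. A list entry was dropped where the reference gives another symbol, which removed 40 of 383 entries. Besides, 2 lists (asperthecin and cell wall synthesis) had fewer than 3 tested genes, which left 31 lists. They cover 13 biosynthetic clusters, backbone enzymes of secondary metabolism, its regulators, development, carbon, nitrogen and iron use, stress, autolysis, nutrient-signalling kinases, cell cycle, autophagy and transformation marker loci, and they overlap. Lists were tested with camera (limma 3.58.1) at the preset correlation of 0.01, with an estimated correlation, and with fry, adjusted over the lists of a contrast. Camera compares a list with all other genes, and fry does not.

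Gene symbols come from the reference gene table of assembly ASM1142v1, in which 9967 genes were matched and 778 carry a symbol, and otherwise from general knowledge. It served for names and gene order only. Genes named in the text are AN7572, the 5 called genes with the highest and lowest change among those with a mean of at least 10 CPM, up to 3 called members per list with the largest change (or the member with the smallest p where none was called), and stcA, aflR, ipnA, orsA, mdpG, laeA, veA, brlA, acuD and creA, with some left out for length. Genes that bound runs along chromosomes were chosen after their values were seen. Reads shared between near-identical genes could not be told apart, since no sequence was used here.

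Alternatives were RLE and upper-quartile scaling, DESeq2 1.42.0, limma-voom, no filter, a filter of at least 5 CPM in at least 2 libraries, a replicate block, a fit of only the groups compared, an adjusted p under 0.01, and each library left out in turn. The edgeR steps were tested on simulated data for the deletion comparison at 17 h (8691 genes). They recovered 30 of 50 genes changed by 0.5 on the log2 scale, 49 of 50 changed by 1 and 50 of 50 changed by 2 or by 4, with 7 unchanged genes called. The changed genes were drawn from those with over 50 expected counts per library. The overlap of calls was simulated 50 times with unchanged strains and the same controls.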

Results

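RNA-seq counts of poly(A) RNA were collected from Aspergillus nidulans grown in liquid minimal medium with 50 mM glucose and 10 mM nitrate at 37 °C. The 12 libraries formed 6 groups of 2, and the labels describe each pair as duplicate cultures. Strain A1153 (wild type) was sampled at 17 h and 48 h, a strain labelled rimO deletion at 17 h and 54 h, and a strain labelled rimO overexpression at 17 h and 48 h. The labels call 17 h a condition of primary metabolism and the later harvests a condition of secondary metabolism, taken 8 h after glucose had run out. The deletion strain took up glucose more slowly per the labels, so its late harvest came at 54 h, and strain and hour cannot be separated there. Libraries held 9269951 to 17891416 counts, and log2 CPM (counts scaled to library size) of the 2 cultures of a group correlated across genes at r = 0.9921 to 0.9943. Levels below are means ± SD in CPM (n = 2 cultures), and changes are edgeR log2 fold changes with an SE and Benjamini-Hochberg adjusted p. The SE was derived as the size of the change over the square root of its F statistic. It is not an edgeR estimate and can be too small where a group holds few counts.

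The targeted gene was examined in every library. The series title names RimO a homolog of the yeast nutrient-signalling kinase Rim15p. No file or reference table names rimO, and AN7572 was taken for it from general knowledge. In wild type AN7572 stood at 99.8 and 109 CPM at 17 h and at 447 and 437 CPM at 48 h. The libraries labelled rimO deletion still held 60.5 and 67.4 CPM at 17 h and 51.6 and 48.4 CPM at 54 h. The libraries labelled rimO overexpression held 588 and 504 CPM at 17 h and 322 and 357 CPM at 48 h. Against wild type AN7572 fell by 0.71 ± 0.10 at 17 h (adjusted p = 0.00305) and by 3.14 ± 0.10 at the late harvest (adjusted p = 1.77e-12) in the libraries labelled deletion. In those labelled overexpression it rose by 2.38 ± 0.10 at 17 h (adjusted p = 7.64e-10) and fell by 0.38 ± 0.09 at 48 h (adjusted p = 0.0047). The residual reads go partly against the deletion label, and at 48 h the overexpression label goes against the counts, so groups are named by their labels throughout. Leaving out 1 library ended the 17 h deletion call (adjusted p = 0.071 without wild type replicate 2 at 17 h, 0.0699 without replicate 1 of the deletion-labelled strain) and the 48 h overexpression call (adjusted p = 0.0514 without replicate 1 of that strain). Directions below compare labelled strains, and at 48 h the overexpression strain did not have more AN7572 transcript than wild type.

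**Figure D1:**
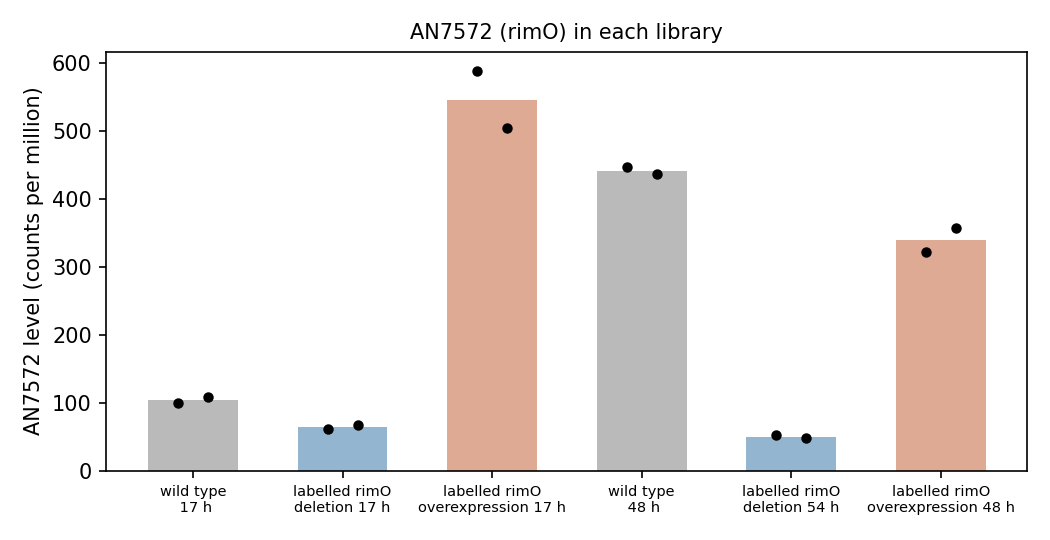
AN7572 (rimO) in each of the 12 libraries, in CPM on an axis from 0, by labelled strain and harvest; bars are group means and points single cultures. The libraries labelled rimO deletion lie between 48.4 and 67.4 CPM, and those labelled rimO overexpression exceed wild type at 17 h and lie below it at 48 h.

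Wild type at 48 h was compared with 17 h to show the move from growth on glucose to glucose exhaustion. All 21 tested genes of the sterigmatocystin cluster, which makes a polyketide mycotoxin, rose, with a median log2 change of 10.50. The cluster's polyketide synthase gene stcA (AN7825) went from 3.41 ± 0.733 to 3380 ± 885 CPM (log2 change 9.92 ± 0.27, adjusted p = 1.41e-13). Its regulator aflR (AN7820) went from 0.0806 ± 0.0181 to 197 ± 25.0 CPM. AN7809 of the same cluster had no count at 17 h and stood at least 9960-fold higher at 48 h. The conidiation regulator brlA (AN0973) rose from 1.23 ± 0.109 to 171 ± 27.4 CPM and the spore-wall hydrophobin gene rodA (AN8803) from 0.369 ± 0.138 to 1070 ± 370 CPM. The autolytic chitinase gene chiB (AN4871) rose from 54.1 ± 2.15 to 3030 ± 168 CPM.

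All 10 glycolysis and fermentation genes fell, and pyruvate decarboxylase pdcA (AN4888) went from 9480 ± 448 to 107 ± 8.36 CPM. Of 13 genes for the glyoxylate cycle, gluconeogenesis, acetate and fatty acid use, 12 rose and 1 fell, with isocitrate lyase acuD (AN5634) up by 3.08 ± 0.13 (adjusted p = 2.17e-11). Of 13 nitrogen assimilation genes 10 fell and 3 rose (camera adjusted p = 0.00604; adjusted p = 0.435 with an estimated correlation), with nitrate reductase niaD (AN1006) at 941 ± 21.3 CPM at 17 h and 0.430 ± 0.212 CPM at 48 h. Of 12 siderophore and iron genes, 9 fell and 2 rose. All 3 penicillin genes fell and all 5 orsellinic acid genes rose. All 5 autophagy genes rose, and 8 of 9 histone and cell cycle genes fell. In total 3893 genes rose and 4155 fell among 9670 tested. Of 31 gene lists, 12 passed the set test camera with its preset correlation, led by sterigmatocystin (adjusted p = 1.31e-25; adjusted p = 0.151 with an estimated correlation) and glycolysis (adjusted p = 1.27e-05; adjusted p = 0.181 with an estimated correlation). None of the 12 passed with an estimated correlation, under which camera passed 0 lists, while fry, which asks whether the genes of a list move 1 way, passed 27. Between early and late harvests, another scaling of the libraries moved the median of all genes. RLE scaling moved it by 0.111 in wild type, 0.093 in the deletion-labelled and 0.143 in the overexpression-labelled strain, and upper-quartile scaling by 0.194, 0.162 and 0.204.

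The libraries labelled rimO deletion were compared with wild type at 17 h to ask what the strain's label goes with during growth on glucose. Few transcripts differed, and most of those were lower. Of 12 siderophore and iron genes 4 were lower, 8 were not called, and 11 were called when adjusted over the list alone. The siderophore gene sidI (AN0609) went from 21.0 ± 2.72 CPM in wild type to 9.17 ± 1.52 (log2 change -1.17 ± 0.16, adjusted p = 0.00235), and the siderophore transporter mirB (AN8540) from 156 ± 2.31 to 74.6 ± 17.0 CPM (adjusted p = 0.0198). Of 3 penicillin genes, isopenicillin N synthase ipnA (AN2622) and aatA (AN2623) fell, by 0.85 ± 0.15 and 0.86 ± 0.18 (adjusted p = 0.0128 and 0.0249), and all 3 were called when adjusted over the list alone. Of 13 stress genes 5 fell, 0 rose and 8 were called when adjusted over the list alone, among them the peroxiredoxin gene prxA (AN8692, -0.65 ± 0.09, adjusted p = 0.00371). The largest falls among genes of at least 10 CPM were AN9184, from 137 ± 8.44 to 33.7 ± 5.85 CPM (log2 change -2.01 ± 0.20, adjusted p = 0.00046), and AN3555, from 1920 ± 102 to 579 ± 161 CPM. The largest rise was AN2177, from 31.8 ± 2.91 to 61.3 ± 9.45 CPM (log2 change 0.95 ± 0.14, adjusted p = 0.00379). The libraries labelled overexpression at 17 h also held less AN9184 and AN3555 than wild type, 39.2 ± 14.7 and 591 ± 213 CPM. They held less prxA and sidI too (2240 ± 161 and 6.4 ± 0.944 CPM), but mirB (158 ± 11.9 CPM) was not lower and AN2177 (19.9 ± 0.16 CPM) not higher. Falls seen in both strains are not particular to the deletion label, and both comparisons share the wild type libraries.

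The sterigmatocystin genes were low in both strains at 17 h, and none of 21 was called. Transcripts of stcA stood at 3.41 ± 0.733 CPM in wild type and 2.77 ± 0.979 in the libraries labelled deletion (adjusted p = 0.834), those of laeA (AN0807), a global regulator of secondary metabolism, at 23.4 ± 0.632 and 22.4 ± 0.174 CPM (adjusted p = 0.885), and those of the carbon catabolite repressor creA (AN6195) at 190 ± 3.50 and 169 ± 15.6 CPM (adjusted p = 0.547). Across all genes 35 rose and 126 fell, 34 of them by at least 2-fold, and 1143 had an unadjusted p under 0.05. Camera with the preset correlation passed 5 lists, with adjusted p = 1.06e-20 for siderophores, 4.41e-07 for penicillin, 6.32e-06 for stress, 0.00097 for glycolysis and 0.00882 for secondary metabolite backbone enzymes, of which 1 of 39 fell. With an estimated correlation none passed (adjusted p = 0.0604, 0.0604, 0.403, 0.46 and 0.998 with an estimated correlation, in that order). In glycolysis 0 of 10 genes were called, and 5 when adjusted over the list alone. The 161 calls became fewer without wild type replicate 1 at 17 h, wild type replicate 2 or replicate 1 of the deletion-labelled strain. Each of these fits left 1 library in a group, so fewer samples were tested by construction. Without any 1 of the libraries compared, the log2 change of ipnA lay between -0.94 and -0.75, against -0.85 with all. Among the named genes, ipnA and aatA were not called without any 1 of the 4 libraries compared (adjusted p = 0.0779 to 0.126 and 0.118 to 0.223), mirB without the 3 libraries just named (adjusted p = 0.118, 0.166 and 0.254) or with DESeq2 (adjusted p = 0.0563), sidI and AN3555 without replicate 1 of the deletion-labelled strain (adjusted p = 0.052 and 0.0779), AN2177 without wild type replicate 2 (adjusted p = 0.089), and prxA without either of the last 2 named (adjusted p = 0.071 and 0.0772).

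At the late harvest, the libraries labelled rimO deletion at 54 h were compared with wild type at 48 h to ask how the strain responds once glucose is gone. All 21 sterigmatocystin genes were lower, with a median log2 change of -7.69. Transcripts of stcA stood at 2.24 ± 0.819 CPM against 3380 ± 885 in wild type (log2 change -10.56 ± 0.27, adjusted p = 1.85e-13) and those of aflR at 2.39 ± 0.00453 against 197 ± 25.0 CPM (-6.36 ± 0.14, adjusted p = 4.88e-14). All 4 emericellamide genes fell (median -5.27), as did all 3 tested terrequinone genes (median -6.76), 5 of 6 monodictyphenone genes, and 8 of 11 austinol genes, of which 1 rose and 10 were called when adjusted over the list alone. The median of the monodictyphenone list was -4.83, or -4.23 with genes that had no count in a group set at their bound, and that of the austinol list -4.86, or -2.84 at the bound.

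Other biosynthetic clusters were higher. All 11 genes of the dba cluster rose, with a median log2 change of 7.34, and AN7895 went from 2.67 ± 1.72 to 4500 ± 374 CPM (log2 change 10.72 ± 0.36, adjusted p = 2.58e-12). In the asperfuranone list 5 of 5 were higher than in wild type, in the fellutamide list 4 of 4, and in the aspyridone list 4 of 5. In the pimaradiene list 5 of 6 were higher, and in the cichorine list 4 of 7 with 1 lower. Levels could be low, as for AN1031 of the asperfuranone list (4.48 ± 0.441 CPM). Higher than wild type did not always mean a rise within the strain from 17 h to 54 h. There apdA (AN8412, aspyridone) went from 31.7 to 15.2 CPM and AN1593 (pimaradiene) from 21.2 to 2.53 CPM, while AN8414 (aspyridone) went from 1.26 to 13.7 CPM. The orsellinic acid cluster split, with orsA (AN7909) lower by 2.61 ± 0.20 (adjusted p = 1.89e-08) and orsE (AN7914) higher by 2.35 ± 0.22 (adjusted p = 2.25e-07). Of 3 penicillin genes 2 rose, while ipnA stood at 6.18 ± 0.0486 and 7 ± 1.73 CPM (adjusted p = 0.391). Of the 39 tested backbone enzyme genes, which overlap the cluster lists, 13 rose and 21 fell. Of the 116 tested genes in the 13 cluster lists or the backbone enzyme list, 45 were higher, 57 lower and 14 not called, and 103 were called when adjusted over the list alone. Among 11 regulators of secondary metabolism and velvet proteins 2 rose and 4 fell, with laeA lower by 0.46 ± 0.09 (adjusted p = 0.000246) and veA (AN1052) by 0.43 ± 0.08 (adjusted p = 0.000184).

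**Figure D2:**
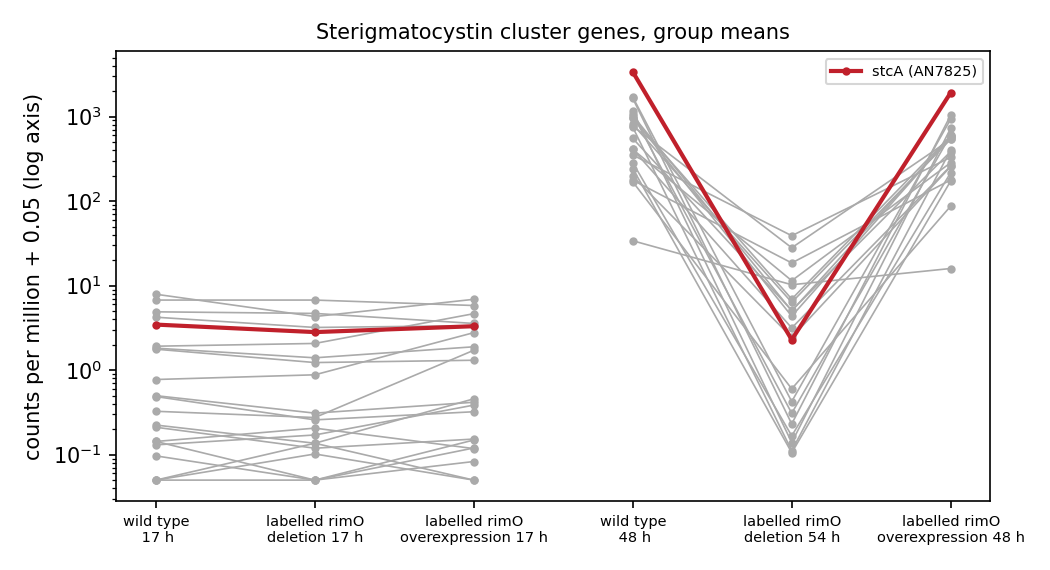
Levels of the 21 tested sterigmatocystin genes by group, in CPM on a log axis with 0.05 added; each grey line is a gene (mean of 2 cultures) and the red line is stcA, at 3380 CPM in wild type at 48 h, 2.24 in the libraries labelled rimO deletion at 54 h and 1920 in those labelled rimO overexpression at 48 h.

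Most conidiation, sexual development and autolysis genes were lower, though none of these lists passed camera with an estimated correlation. Of 15 conidiation genes 12 fell and 3 rose. Transcripts of rodA stood at 0.634 ± 0.202 CPM against 1070 ± 370 in wild type (log2 change -10.69 ± 0.30, adjusted p = 4.52e-13) and those of brlA at 3.29 ± 0.811 against 171 ± 27.4 CPM (-5.71 ± 0.16, adjusted p = 3.81e-13). Of 16 sexual development genes 10 fell and 5 rose. Of 6 autolysis genes 4 fell and 1 rose, with chiB at 40.7 ± 0.167 against 3030 ± 168 CPM. All 5 trehalose and mannitol genes fell, and so did all 6 nutrient-signalling kinase genes, a list that holds AN7572 itself, with schA (AN4238) lower by 1.85 ± 0.12 (adjusted p = 2.41e-09).

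Siderophore genes and most nitrogen assimilation genes were higher. All 12 siderophore and iron genes rose (median 5.39), with sidI at 400 ± 56.9 against 0.284 ± 0.0736 CPM (log2 change 10.41 ± 0.22, adjusted p = 3.03e-14) and mirB at 1270 ± 159 against 5.67 ± 2.60 CPM. Of 13 nitrogen assimilation genes 9 rose and 2 fell, with niaD at 45.4 ± 5.36 against 0.430 ± 0.212 CPM. The glucose transporter gene mstE (AN5860) stood at 976 ± 18.3 against 2.62 ± 0.258 CPM, while 6 of the 9 genes of the hexose uptake and carbon repression list fell. Transcripts of pdcA were higher by 3.62 ± 0.14 (adjusted p = 1.02e-11), 5 of 10 glycolysis genes rose and 4 fell, and in the glyoxylate list 3 rose and 6 fell with acuD at 310 ± 10.1 and 313 ± 13.1 CPM (adjusted p = 0.914). Of 19 plant polysaccharide hydrolase genes and regulators 11 rose and 6 fell, of 6 proline and purine genes 2 rose and 3 fell, of 13 stress genes 3 rose and 5 fell, and of 9 histone and cell cycle genes 5 rose and 4 fell. Of 5 autophagy genes 1 rose and 4 fell, and of 5 transformation marker loci 4 rose and 1 fell.

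Across all genes 3884 rose and 3849 fell between these groups, of which 2327 and 1744 changed at least 2-fold. Camera passed 11 lists with the preset correlation, and 2 of them also with an estimated correlation, emericellamide (adjusted p = 5.82e-07; adjusted p = 0.0333 with an estimated correlation) and dba (adjusted p = 7.74e-20; adjusted p = 0.0333 with an estimated correlation). The other passing lists were sterigmatocystin (adjusted p = 1.2e-32), siderophores (5.06e-11), autolysis (0.000121), conidiation (0.00453) and terrequinone (0.00999), each with adjusted p = 0.0997 with an estimated correlation. Nutrient-signalling kinases passed at 0.0261 (adjusted p = 0.14 with an estimated correlation), sexual development at 0.0448 (adjusted p = 0.346 with an estimated correlation), and nitrogen assimilation and backbone enzymes at 0.0465 each (adjusted p = 0.539 with an estimated correlation for each). Fry passed 28 lists.

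From 17 h to 54 h the libraries labelled rimO deletion showed part of the change seen in wild type. All 10 glycolysis genes fell and 11 of 13 glyoxylate and acetate genes rose, with acuD from 45.6 ± 5.95 to 313 ± 13.1 CPM. All 5 autophagy genes rose and all 9 histone and cell cycle genes fell. In the sterigmatocystin cluster 10 of 21 genes rose, while stcA stood at 2.77 ± 0.979 and 2.24 ± 0.819 CPM (adjusted p = 0.334), and aflR went from 0.121 ± 0.0245 to 2.39 ± 0.00453 CPM (adjusted p = 1.24e-06). All 12 siderophore genes rose, all 11 dba genes rose and all 4 emericellamide genes fell. In total 3996 genes rose and 3798 fell. Camera passed 11 lists, and with an estimated correlation 1 of them, emericellamide (adjusted p = 2.75e-08; adjusted p = 0.032 with an estimated correlation), but neither dba (adjusted p = 0.129 with an estimated correlation) nor siderophores (adjusted p = 0.265 with an estimated correlation).

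The late-minus-early change was then compared between the deletion-labelled strain and wild type by an interaction test. The difference was called for 6458 genes, 3289 positive and 3169 negative. For the siderophore list all 12 differences were positive (sidI 11.58 ± 0.28, adjusted p = 7.28e-13), for dba all 11 were positive, for emericellamide all 4 were negative, and for sterigmatocystin 17 of 21 were negative, including stcA (-10.29 ± 0.50, adjusted p = 3.84e-10) and aflR (-6.97 ± 1.39, adjusted p = 0.000496). The difference of acuD was -0.31 ± 0.18 and was not called (adjusted p = 0.146). Of the 9 lists that camera passed, emericellamide also passed with an estimated correlation (adjusted p = 0.0164 with an estimated correlation), and siderophores gave adjusted p = 0.059, dba and sterigmatocystin 0.486 each with an estimated correlation.

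At 17 h, the libraries labelled rimO overexpression were compared with wild type to ask what more AN7572 transcript goes with during growth on glucose. Transcripts of 3 proline genes fell most in their list. Proline oxidase prnD (AN1731) went from 1040 ± 41.9 to 0.781 ± 0.0166 CPM (log2 change -10.36 ± 0.25, adjusted p = 2e-12), prnC (AN1733) from 717 ± 23.4 to 6.05 ± 1.44 CPM, and the proline permease gene prnB (AN1732) from 270 ± 16.8 to 9.43 ± 0.774 CPM. In the same cluster prnX (AN1730) fell by 1.57 ± 0.09 (adjusted p = 2.01e-08) and prnA (AN1729) was not called (-0.10 ± 0.09, adjusted p = 0.428), both named after their values were seen. Of the 6 tested genes of the proline and purine list 4 fell, 0 rose and 5 were called when adjusted over the list alone. AN1734, next to these genes, and AN2901 were also among the 5 largest falls, AN2901 from 1760 ± 42.8 to 37.3 ± 0.229 CPM. The alpha-glucosidase gene agdB (AN8953) showed the largest rise, from 3.26 ± 0.656 to 1310 ± 25.6 CPM (8.62 ± 0.34, adjusted p = 5.47e-10), and 7 of 19 plant polysaccharide genes rose and 4 fell.

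All 4 emericellamide genes and all 3 penicillin genes fell, with ipnA lower by 1.89 ± 0.16 (adjusted p = 1.09e-06). Of 12 siderophore genes 7 fell, 1 rose and 9 were called when adjusted over the list alone. Of 39 backbone enzyme genes 14 fell and 2 rose, and of the same 116 cluster or backbone genes 9 rose, 21 fell and 29 were called when adjusted over the list alone. Of 16 sexual development genes 6 rose and 0 fell, with esdC (AN9121) up from 30.8 ± 2.59 to 151 ± 1.36 CPM. The conidiation gene fluG (AN4819) fell from 775 ± 34.4 to 62.1 ± 9.76 CPM (adjusted p = 6.48e-11). Transcripts of acuD fell by 1.28 ± 0.15 (adjusted p = 2.06e-05), and laeA rose by 0.49 ± 0.10 (adjusted p = 0.00165). Across all genes 1456 rose and 1398 fell, 457 and 343 of them at least 2-fold. Camera passed 7 lists, and proline and purine catabolism (adjusted p = 6.35e-50; adjusted p = 0.000437 with an estimated correlation) and emericellamide (adjusted p = 8.69e-07; adjusted p = 0.0274 with an estimated correlation) also with an estimated correlation. The others were plant polysaccharides (0.000955, with adjusted p = 0.163 with an estimated correlation), penicillin (0.00161, with adjusted p = 0.163 with an estimated correlation), siderophores (0.00161, with adjusted p = 0.496 with an estimated correlation), sexual development (0.00294, with adjusted p = 0.203 with an estimated correlation) and backbone enzymes (0.00294, with adjusted p = 0.496 with an estimated correlation). The 2854 calls became 1813 without wild type replicate 1 at 17 h, 1782 without wild type replicate 2 and 1873 without replicate 2 of the overexpression-labelled strain.

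At 48 h, the libraries labelled rimO overexpression were compared with wild type after glucose exhaustion, when their AN7572 transcript was no higher. All 3 penicillin genes rose, with ipnA from 6.18 ± 0.0486 to 76.3 ± 1.85 CPM (log2 change 3.62 ± 0.15, adjusted p = 1.07e-09). Of 12 siderophore genes 10 rose (median 2.22), of 11 austinol genes 10 rose (median 2.56), and all 3 terrequinone genes rose. All 11 dba genes fell (median -4.04, or -3.45 with genes at no count in a group set at their bound). Levels were low and spread between cultures in wild type, as for AN7902 (4.67 ± 2.25 CPM, against 0.0929 ± 0.00391) and AN7895 (2.67 ± 1.72 CPM, against 0.462 ± 0.112). In the sterigmatocystin cluster 18 of 21 genes fell and 1, aflR, rose, by small amounts, with a median of -0.66 and stcA at 1920 ± 195 against 3380 ± 885 CPM (-0.82 ± 0.17, adjusted p = 0.00154). Of 5 orsellinic acid genes 4 fell. Transcripts of laeA stood at 122 ± 11 against 50.7 ± 0.761 CPM (1.27 ± 0.08, adjusted p = 4.49e-08).

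Autolysis genes rose in 5 of 6 cases, with chiB at 6310 ± 731 against 3030 ± 168 CPM and the protease gene prtA (AN5558) up by 2.11 ± 0.16 (adjusted p = 1.95e-07). The metalloprotease gene pepJ (AN7962, listed as mep20 in the reference) rose most, from 20.4 ± 10.1 to 1120 ± 148 CPM (5.77 ± 0.25, adjusted p = 4.35e-09). Conidiation genes went both ways, with 7 of 15 higher and 3 lower, and rodA rose by 1.75 ± 0.18 (adjusted p = 2.56e-06). Of 13 stress genes 9 fell and 2 rose, with the catalase gene catA (AN8637) at 2.79 ± 0.0143 against 16.4 ± 1.17 CPM. All 5 trehalose and mannitol genes fell, with trehalase treA (AN9340) at 88.3 ± 3.02 against 298 ± 77.4 CPM. Of 10 glycolysis genes 6 fell and 1 rose, with 8 called when adjusted over the list alone, 9 of 19 plant polysaccharide genes rose, and acuD fell by 1.86 ± 0.12 (adjusted p = 4.49e-08). In total 2220 genes rose and 1754 fell, 503 and 588 of them at least 2-fold. Of the 116 cluster or backbone genes 28 rose and 40 fell, and 68 were called when adjusted over the list alone.

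Camera passed 13 lists in this comparison with the preset correlation and 0 with an estimated correlation, while fry passed 17. The smallest were siderophores (adjusted p = 1.11e-11; adjusted p = 0.143 with an estimated correlation), penicillin (2.72e-09; adjusted p = 0.0716 with an estimated correlation), trehalose and mannitol (3.62e-07; adjusted p = 0.143 with an estimated correlation), dba (9.39e-07; adjusted p = 0.261 with an estimated correlation), stress (4.88e-06; adjusted p = 0.189 with an estimated correlation), autolysis (2.23e-05; adjusted p = 0.112 with an estimated correlation), austinol (2.52e-05; adjusted p = 0.143 with an estimated correlation) and sterigmatocystin (0.000354; adjusted p = 0.543 with an estimated correlation). Nutrient-signalling kinases, with 4 of 6 lower, gave 0.00813 (adjusted p = 0.143 with an estimated correlation), glycolysis 0.0265 (adjusted p = 0.418 with an estimated correlation), plant polysaccharides 0.034 (adjusted p = 0.285 with an estimated correlation), and orsellinic acid and terrequinone 0.0399 each (adjusted p = 0.511 and 0.202 with an estimated correlation).

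**Figure D3:**
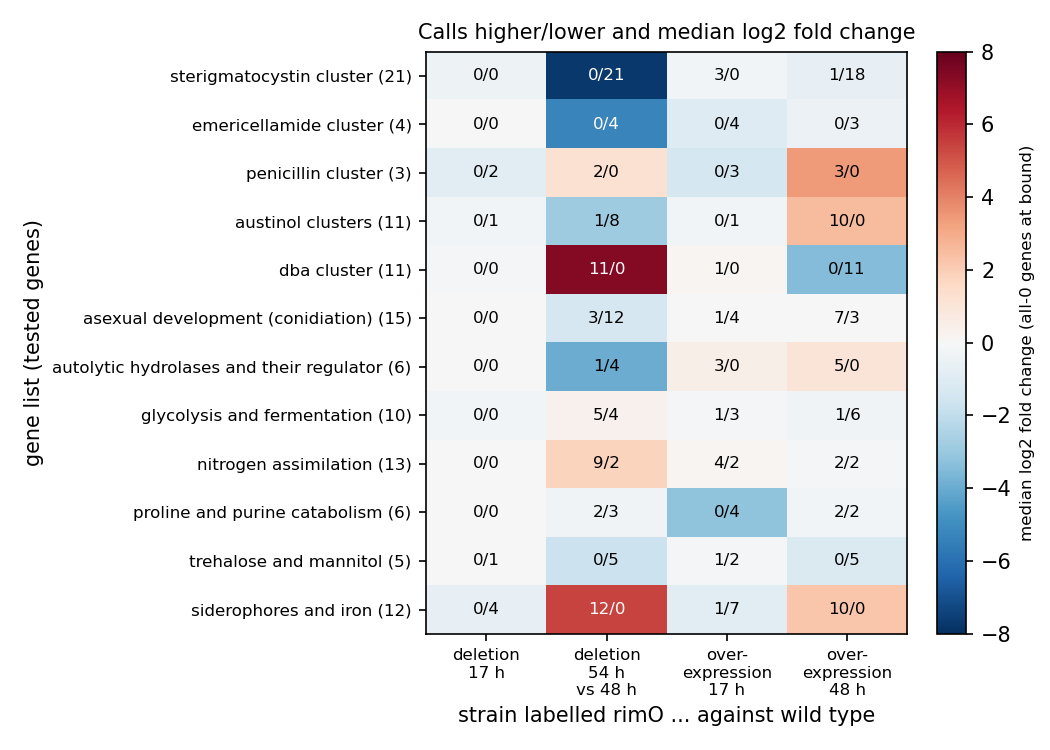
Median log2 fold change of 12 gene lists in the 4 comparisons with wild type; genes with no count in a group stand at their bound, the colour scale runs from -8 (blue) to 8 (red), and each cell gives the calls higher/lower. Most called siderophore genes were lower at 17 h and all called ones higher at the late harvest in both labelled strains, and the dba cluster went opposite ways at the late harvest.

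From 17 h to 48 h the libraries labelled rimO overexpression were compared within the strain. All 21 sterigmatocystin genes rose (stcA from 3.26 ± 0.157 to 1920 ± 195 CPM), all 6 autolysis genes rose, and all 10 glycolysis genes fell. The penicillin genes, which fell in wild type, all rose here, with ipnA from 6.77 ± 1.55 to 76.3 ± 1.85 CPM (adjusted p = 2.71e-11). In total 3696 genes rose and 4216 fell. Camera passed 13 lists and 0 with an estimated correlation, with sterigmatocystin at adjusted p = 2.65e-26 (adjusted p = 0.113 with an estimated correlation) and autolysis at 8.96e-09 (adjusted p = 0.0581 with an estimated correlation). The difference from wild type in the late-minus-early change was called for 2792 genes, 1259 positive and 1533 negative. It was positive for all 3 penicillin genes (ipnA 5.51 ± 0.22, adjusted p = 1.3e-09), for 10 of 12 siderophore genes and for 5 of 6 proline and purine genes, and negative for 10 of 11 dba genes. Of 9 lists that camera passed, penicillin (adjusted p = 0.00497 with an estimated correlation) and proline and purine catabolism (adjusted p = 0.00271 with an estimated correlation) also passed with an estimated correlation, and siderophores (adjusted p = 0.0545 with an estimated correlation) and dba (adjusted p = 0.531 with an estimated correlation) did not. The difference of stcA was not called (-0.73 ± 0.36, adjusted p = 0.151), but was without wild type replicate 2 at 48 h (-0.93, adjusted p = 0.0346).

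Calls of both labelled strains were set side by side at each harvest. At 17 h, 126 genes were called in both comparisons, 13 higher and 91 lower in both and 22 in opposite directions. Independent lists of these sizes would share 5.3 higher and 18.2 lower genes. Of the opposite calls at 17 h, 8 were lower and 14 higher in the deletion-labelled strain (19 and 5.1 for independent lists). At the late harvest 3329 genes were called in both, 828 higher and 929 lower in both (891.7 and 698.2 for independent lists) and 1572 in opposite directions. Of these, 994 were lower and 578 higher in the deletion-labelled strain (883.6 and 704.5 for independent lists). Both comparisons use the same wild type libraries, and 50 simulations of unchanged strains gave a median of 0 genes in the same direction at either harvest, with at most 5 and 2. Each simulated fit held only the libraries of 1 harvest. Unchanged strains give few calls, so these counts do not show how much shared controls add where many genes are called. Fold changes correlated across genes at 0.25 at 17 h and 0.06 at the late harvest, and shared controls alone gave 0.5 and 0.49. The covariance was 0.042 at 17 h and 0.109 at the late harvest, against 0.014 at each from shared controls alone. The controls were not split, since each part would keep 1 library, and part of the overlap may come from the shared controls. The 104 genes called in the same direction at 17 h became 33 and 18 without wild type replicate 1 or 2 at 17 h and 12 without replicate 1 of the deletion-labelled strain.

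Called genes were also placed in chromosome order, since fungal biosynthetic genes lie in clusters. A run was counted where at least 5 of 6 neighbouring tested genes were called in the same direction. Against wild type at 48 h, the libraries labelled overexpression had 55 runs of higher and 35 of lower genes, and those labelled deletion at 54 h 210 and 229. In 100 random gene orders the most runs were 28 and 13 for overexpression and 164 and 175 for deletion. At 17 h the overexpression comparison had 10 runs of higher and 16 of lower genes (at most 8 and 6 in random orders), including the proline genes up to AN1734 and the emericellamide genes AN2545 to AN2549. The deletion comparison had 0 in either direction at 17 h, also 0 in random orders. Positions came from the order of the 9095 matched genes on 8 chromosomes of the reference assembly.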

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

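The tests of explanations below were all chosen only after the results were seen, while the interaction tests were planned. The change from the early to the late harvest differed between strains. It differed from wild type for 6458 genes and 9 gene lists in the strain labelled rimO deletion, and for 2792 genes and 9 gene lists in the strain labelled rimO overexpression. The lists are those passing camera with its preset correlation, and with an estimated correlation 1 and 2 passed. For deletion the log2 differences called among the genes always reported were stcA -10.29, aflR -6.97, brlA -5.54, orsA -3.62, mdpG (AN0150, tpcC in the reference) -1.89, ipnA 1.02, creA 0.51, laeA -0.40 and veA -0.35. For overexpression they were ipnA 5.51, laeA 0.78, acuD -0.58 and creA -0.46. Leaving out 1 library ended some of these calls. For deletion these were orsA (adjusted p = 0.102 and 0.0649 without wild type replicate 1 or 2 at 17 h, 0.0585 and 0.334 without replicate 1 or 2 of the deletion-labelled strain at 17 h, 0.0509 without its replicate 2 at 54 h), laeA and veA (0.0562 and 0.0536 without wild type replicate 2 at 17 h, 0.0502 and 0.0691 without deletion-labelled replicate 2 at 17 h) and creA (0.0541 without wild type replicate 1 at 48 h). For overexpression acuD was not called without wild type replicate 1 or 2 at 17 h (0.0627 and 0.115) or at 48 h (0.0982 and 0.0654), deletion-labelled replicate 2 at 54 h (0.0606), overexpression-labelled replicate 1 at 17 h (0.169) or replicate 2 at 48 h (0.102), nor with limma-voom (0.0519) or a fit of only the groups compared (0.0546). There creA was not called without wild type replicate 1 at 17 h (0.0609) or replicate 2 at 48 h (0.102), or overexpression-labelled replicate 1 at 17 h (0.054) or replicate 2 at 48 h (0.0545). In data outside the comparisons, 1 of the 31 upstream open reading frames held 356 counts over the 12 libraries, between 12 and 43 in each, above the 3 counts that a count of 0 allows.

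AN7572 reads remained in the libraries labelled rimO deletion. If wild-type hyphae or RNA were mixed in, their share would set a floor for every gene, at 61.1% of wild type at 17 h and 11.3% at 54 h. At 17 h, 9 of 2151 genes of at least 100 CPM in wild type lay below that floor by more than 2 SE of each value. At 54 h 95 of 1831 did. This argues against RNA of the sequenced wild-type cultures as the whole source. For hyphae, it takes them to have had the levels of those cultures. On that assumption the 54 h count argues against hyphae as the whole source there. At 17 h it cannot decide, since AN9184 and AN3555 were about as low in the libraries labelled overexpression (39.2 and 591 CPM) as in those labelled deletion (33.7 and 579 CPM). A transcribed part of the locus left by the deletion stays possible, since counts per exon were not used here and the 11.3% kept does not say which part was read. The effect of the residual transcript on the strain is open.

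Late wild-type transcripts were missing from the libraries labelled rimO deletion at 54 h, among them stcA, brlA and chiB. Full carbon repression would keep acetate and glyoxylate genes at their early level, yet 11 of 13 rose from 17 h and acuD stood at the wild-type level, which argues against it for these genes. A mix of early and late hyphae, or a partial move between the wild-type states, would put nearly every gene between them, but 1462 of 2347 genes called at least 2-fold against both lay outside, 1207 above both and 255 below both. The later clock time cannot be told apart from the strain, since 0 deletion libraries were harvested at 48 h. A loss of rimO function, which the label names, may contribute and was not separated from it.

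Transcripts of prnC and prnD were nearly absent from the libraries labelled rimO overexpression at 17 h. An early move toward the late wild-type state would leave them at or above the 48 h level of wild type, but prnC lay below it by a log2 difference of -4.28 ± 0.13 and prnD by -5.76 ± 0.26 (edgeR adjusted p = 6.95e-13 and 4.06e-11). The permease gene prnB and prnX went the other way, 1.30 ± 0.19 and 1.02 ± 0.10 above that level (adjusted p = 1.93e-05 and 1.94e-07), so that the argument holds for prnC and prnD (prnX was named after its values were seen). A loss of the locus is argued against by the rise to 48 h, of 4.86 for prnC and 4.98 for prnD. The raised AN7572 (log2 change 2.38) cannot be told apart from another difference of this 1 strain or its cultures.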

How the results depend on the processing

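The alternatives for the overlap of calls and for list members kept despite another reference symbol were chosen after seeing the data, and the rest were planned. No named gene changed direction where it was called in the main fit or in the alternative. Of 1827 recomputed values for 87 gene results, 1775 kept their side of the threshold, 51 lost it and 1 gained it. At an adjusted p under 0.01, which is stricter by construction, calls were 42 for deletion at 17 h (161 in the report), 1743 for overexpression at 17 h (2854), 1808 for the overexpression interaction (2792), and the 17 h overlap 30 (104). Over the 9 contrasts 90 list tests passed camera, 8 with an estimated correlation and 182 with fry. Without 1 library, calls ranged from 16 to 190 for deletion at 17 h, 7277 to 7825 for deletion at the late harvest, 1782 to 2908 and 2735 to 4010 for overexpression at 17 h and 48 h, 12 to 125 for the overlap at 17 h and 1243 to 1764 at the late harvest. A group left with 1 library was assumed to vary like the others, fewer samples are tested there by construction, and beyond that the cause was not tested. DESeq2 gave the most calls for deletion at 17 h, 235, and no scaling, filter or tool, DESeq2 included, moved a count of calls by more than 1.5 times. Cluster or backbone genes called at the late deletion harvest (102) numbered 73 with at least 5 CPM in 2 libraries, with fewer genes tested, 109 with no filter, and also 109 with all list members kept. All 9 contrasts kept their count of calls within 1.5 times with a replicate block, with 129 calls for deletion at 17 h and 91 list tests. Deviations of cultures with the same replicate number correlated at -0.15 to 0.1 over 15 pairs of groups and 0 exceeded 0.1. Replicate numbers were given here in the order of the samples. The titles carry other numbers, which run the opposite way for overexpression at 48 h. Neither these correlations nor the replicate block can therefore exclude another pairing of cultures. Tests on the deposited log2 RPKM were not run because they hold 1 value per group. Runs of at least 4 of 5 neighbours also exceeded random orders in the overexpression comparisons and at 54 h, with 105 higher and 70 lower for overexpression at 48 h (at most 75 and 37 in random orders), and deletion at 17 h had 1 run of lower genes (at most 0 in random orders). With 2 cultures per group, changes under 2-fold at 17 h would be partly missed, as the simulated 30 of 50 at 0.5 show. The changed genes of that simulation had over 50 expected counts per library, so it does not cover genes with fewer counts.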

Other observations

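The tests of chromosome ends and of opposite directions were chosen only after the results were seen, and the test of neighbouring genes was planned. At the late harvest the libraries labelled rimO deletion had long blocks of called neighbours, AN7804 to AN7828 (27 of 27 genes lower), which spans the sterigmatocystin genes stcA and aflR, and AN7865 to AN7903 (38 of 38 higher), which spans the dba gene AN7895. In the libraries labelled rimO overexpression at 48 h the block AN7892 to AN7903 was lower (13 of 13), and AN9243 to AN9259 was higher (15 of 16 called). These blocks were chosen after their values were seen. In that comparison 55 runs of higher genes stood against at most 28 in 100 random orders, so that the response may act on chromosome neighbourhoods, though genes of 1 pathway also lie side by side.

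Genes called with a change of at least 2-fold were more frequent near chromosome ends, except in the deletion comparison at 17 h. Among the 50 outermost tested genes at each end (800 genes), 16.9% were higher at 48 h in the libraries labelled overexpression, against 4.11% elsewhere (permutation by 1000 rotations of the gene order, 1-sided p = 0.00799, Benjamini-Hochberg adjusted over 8 tests 0.018). For lower genes there the shares were 8.62% and 5.8% (adjusted p = 0.024), and at 17 h 11.4% and 4.05% for higher (0.018) and 6.38% and 3.21% for lower genes (0.0192). In the libraries labelled deletion at 54 h they were 42.4% and 21.9% for higher (0.016) and 28.1% and 17.1% for lower genes (0.018), while at 17 h neither direction passed (adjusted p = 0.103 and 0.0514). A position near a chromosome end may go with the response in both labelled strains, and whether the density of biosynthetic genes there accounts for it was not tested.

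Whether lower and higher AN7572 move secondary metabolite genes in opposite directions could not be tested at the late harvest, since AN7572 was lower than wild type in both late comparisons. As values, 27 of 60 genes of the cluster or backbone lists called in both (45%) went opposite ways, against 47.3% of 3269 other genes (Fisher's exact test, 2-sided p = 0.795). At 17 h AN7572 was lower in the deletion-labelled strain (-0.71) and higher in the overexpression-labelled strain (2.38), but no such test was run there. Of 116 cluster or backbone genes, 0 rose and 4 fell in the first, and 9 rose and 21 fell in the second. In both, ipnA (-0.85 and -1.89), aatA (-0.86 and -0.92) and AN8376 (-1.95 and -1.51) fell. These genes were picked because they fell in both, and both comparisons share the wild type libraries at 17 h. No conclusion about direction is therefore drawn from them.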
